A study of Homo sapiens with 3 samples.

How the data were processed

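Gene expression was measured by RNA sequencing of total RNA from LM2 cells, a derivative of the human triple-negative breast cancer line MDA-MB-231 that was selected for spread to the lung. The 3 libraries were 1 control hairpin library (con-sh) and 2 libraries with a hairpin against the circular RNA hsa_circ_0005505 (circ-sh1 and circ-sh2). Their titles give these short names only and do not name the circular RNA. A circular RNA is a transcript whose ends are joined by back-splicing, and a hairpin across that junction can lower it without targeting the linear transcript. The labels do not say whether circ-sh1 and circ-sh2 are separate hairpin sequences or separate cultures of 1 hairpin, so p-values of single genes measure only the spread between these libraries. P-values of gene lists with a preset correlation, described below, take genes and not cultures as the replicates. The libraries circ-sh1 and circ-sh2 were treated as 2 libraries of 1 knockdown group and were also described separately.

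The authors deposited 1 table of FPKM values (fragments scaled by transcript length and by the number of mapped fragments) with a column for each library, per the file headers. HISAT2 and the genome build hg19 are named in the submitters' processing notes. The program that turned alignments into FPKM, its annotation and its filters are not given in the sources used here. The gene identifiers carry the suffixes of a GENCODE annotation mapped back to the earlier build, and coordinates below are those of the table (hg19, counted from 1). The table lists 11380 genes, all of the protein-coding type, and the lowest maximum over the 3 libraries is 0.5 FPKM, so genes below that level in every library were absent before this work began. Circular RNAs, other non-coding RNAs and read counts were not analysed here.

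The 10 rows for Y copies of pseudoautosomal genes were left out, which left 11370 genes. Summed FPKM was 166253 in con-sh, 166918 in circ-sh1 and 165315 in circ-sh2. FPKM carries no read number, and low values of genes with few transcripts showed no common step that would reveal one (the alignment to any step reached at most 0.27 in con-sh against a chance bound of 0.333). The depth of each library is therefore unknown, and no counting interval is given. An exact 0 in such a table can be a failed estimate rather than absent RNA; genes with a 0 are given as listed at 0, without a fold change.

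Values were analysed as log2(FPKM + 1), and differences below are on that scale, which understates changes of weakly expressed genes. Genes with a mean of at least 1 FPKM over the 3 libraries were tested (9946 genes). The design fixed in advance allowed for counts or FPKM; as the table held FPKM, limma 3.58.1 (R 4.3.3) was used, with lmFit and eBayes with a variance trend, both knockdown libraries against the control, and Benjamini-Hochberg adjustment at 0.05. With 2 libraries against 1 there was 1 residual degree of freedom, the lone control was assumed to vary like the knockdown libraries, and the moderation added 2.2 prior degrees of freedom. Each knockdown library against the control is 1 library against 1 and was described by size (2-fold) without a test.

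In all, 39 gene lists of pathways, cell states and other cell types were fixed before the data were examined, and the 31 lists with at least 5 tested members were compared with all other genes by camera (limma) with its preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. For each knockdown library alone, the median of a list was placed among the medians of 10000 random lists of the same size matched on expression in 20 bins. Because both knockdown libraries are compared with the same control, the values expected with no effect were simulated 1000 times from unchanged libraries with the spread between the 2 knockdown libraries in the same bins. Exon numbers were taken from GENCODE release 29 by gene identifier (11319 of 11370 matched) and are the largest number in any transcript of the gene. No coordinate of that release was used.

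The fit of knockdown against control was tested on simulated data for the 9946 genes, with 67 genes changed by 1, 67 by 2 and 66 by 4 on the log2 scale. With a normal spread of SD 0.1, 100% were recovered at each size and 0.0923% of unchanged genes were called. With the spread of the real libraries, 0% were recovered at each size. For a list of 24 genes shifted by 0.5, camera with the preset correlation gave an unadjusted p under 0.05 in 100% of 100 simulated sets, and in 5% with no shift. Genes were simulated independently of each other, so the 5% does not hold for lists whose members vary together. For the correlation of the 2 knockdown libraries, a simulated shared variance of 0.0892 was estimated as 0.0778.

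Genes were named by a rule fixed in advance: the 12 higher and 12 lower genes with the largest value of the smaller of the 2 absolute changes, among genes past the threshold or, where fewer than 5 passed, by size alone, which was the case here; up to 4 members per list in 1 direction by the same ranking; the 3 genes with the largest difference in each direction between the knockdown libraries; and IRAK3 and FOXC1. Any other gene named (such as ISG15, CXCL2, EGLN1 and EIF4A1) was chosen after its values were seen. Some genes that the rule selects are not reported here. The alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, a trimmed-mean scaling to the control, quantile normalization, no variance trend, a size of 1.5-fold, an estimated inter-gene correlation and leaving out each knockdown library. A restriction to genes with 5 or more exons was added after the data were seen. Tests meant for counts were not used.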

Results

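LM2 cells with a hairpin against hsa_circ_0005505 (2 libraries, circ-sh1 and circ-sh2) were compared with cells with a control hairpin (1 library, con-sh), to ask which protein-coding genes differ when this circular RNA is targeted. The table gave FPKM for each gene and library. The median over 11370 genes was 5.23 FPKM in con-sh, 5.14 in circ-sh1 and 5.18 in circ-sh2, and 9809, 9821 and 9755 genes reached 1 FPKM. Values of the knockdown group are given as mean ± SD over its 2 libraries (n = 2); the control has no replicate.

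The circular RNA itself is not among the measured features. It is known to arise from IRAK3, which encodes an inhibitor of Toll-like and interleukin 1 receptor signalling, but a gene-level value is not a value of the circular RNA. IRAK3 (ENSG00000090376, chromosome 12, 66582659 to 66648402, plus strand) stood at 3.59 FPKM in con-sh, 3.42 in circ-sh1 and 1.12 in circ-sh2. The fitted difference was -0.58 ± 0.55 (SE) on the log2 scale, with a limma adjusted p of 1. FOXC1 (ENSG00000054598, chromosome 6, 1610207 to 1614132, plus strand) encodes a forkhead transcription factor linked to invasion of breast cancer cells and is known from the study of this circular RNA, so it is not an independent choice. It stood at 3.59 FPKM in con-sh and was listed at 0 in both knockdown libraries; its limma adjusted p was 0.24. FOXC1 has a single exon, and of 70 single-exon genes that reached 3 FPKM, 39 (55.7%) were listed at 0 in 1 or 2 libraries, against 17 of 7904 multi-exon genes (0.215%; Fisher's exact test across genes, two-sided p = 1e-72, genes not being independent replicates).

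As groups, interferon stimulated, inflammatory, hypoxia response and matrix protease genes were lower in the knockdown libraries than in the control by camera with its preset correlation. YAP and TAZ targets and mitotic genes were higher by the same test. None of these groups passed with an estimated correlation, a version that could hardly pass a list with 1 residual degree of freedom. Among single genes, TIMP2 stood at 103 FPKM in con-sh and 10.5 ± 0.926 in the knockdown group, and MMP1 at 156 and 61.5 ± 1.47, but no gene passed the test. Of 9946 genes, 0 passed limma's test at an adjusted p of 0.05; the lowest adjusted p was 0.112. At an unadjusted p under 0.05 there were 532 genes, 283 higher and 249 lower in the knockdown group, where 497 are expected by chance. More genes reached this unadjusted level when circ-sh1 or circ-sh2 was set against the other 2 libraries, so the excess is not particular to the control. The same fit on simulated libraries with this spread recovered 0% of genes changed by 4 on the log2 scale. A count of 0 at the adjusted threshold therefore does not exclude large changes. By size alone, 160 genes were at least 2-fold higher and 126 at least 2-fold lower than control in both knockdown libraries. Unchanged libraries that share 1 control gave 142 genes in each direction on average, with 95% ranges of 119 to 166 for higher and 120 to 164 for lower genes. Independent lists of the observed lengths would share 9.21 and 13.9 genes. Among genes with 5 or more exons, 74 were higher and 75 lower in both, inside the simulated ranges of 45 to 76 and 44 to 76. Among genes with 1 to 4 exons, 85 were higher (simulated range 61 to 95) and 50 lower, fewer than the simulated range of 62 to 96.

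By size, several of the genes with the largest differences were listed at 0 in the control or in both knockdown libraries. Among the higher genes, GPX1, which encodes a glutathione peroxidase, stood at 1.26 FPKM in con-sh and 170 ± 15.2 in the knockdown group, and ARF6, a small GTPase of membrane traffic, at 4.83 and 73.6 ± 5.88. COA3, a factor of cytochrome c oxidase assembly, was at 0.597 and 24.5 ± 1.13. TRMT10C, a subunit of mitochondrial RNase P, was at 0.00703 and 26.8 ± 1.87, and LSM10, a component of the U7 snRNP, at 0.123 and 12.3 ± 0.13. These genes have few annotated exons (3 for GPX1, 2 for ARF6, 3 for COA3, 2 for TRMT10C and 4 for LSM10), a class of 1 to 4 exons in which 19.1% of genes differed 2-fold between the knockdown libraries themselves. Listed at 0 in con-sh were the linker histone gene H1F0 (213 and 235 FPKM in circ-sh1 and circ-sh2), the general transcription factor gene TAF7 (63.9 and 77.4), PNMA1 (42.5 and 39.8), the selenophosphate synthetase gene SEPHS2 (31.8 and 31.7) and the RNA-binding protein gene HNRNPA0 (33.2 and 31.3). The read-through gene SENP3-EIF4A1 was also listed at 0 in con-sh, with 79.9 and 82.7 FPKM in the knockdown libraries; EIF4A1, which it overlaps on the same strand and which was chosen after its values were seen, stood at 82.4 FPKM in con-sh, 15.1 in circ-sh1 and 20 in circ-sh2, so both values are uncertain. The limma adjusted p of the higher genes named by the rule was 0.11 to 0.2. Of those at 0.11, all but GPX1 were listed at 0 in con-sh, so these p-values rest on possible failed estimates.

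Among the lower genes, TIMP2 (chromosome 17, 76849059 to 76921469, minus strand), an inhibitor of matrix metalloproteinases, differed by -3.18 ± 0.2 (SE) on the log2 scale. SDC4, which encodes the heparan sulfate proteoglycan syndecan 4, was at 229 and 31.3 ± 6.01. The interferon-induced gene IFIT2 was at 11.3 and 0.168 ± 0.035, the antiproliferative gene TOB2 at 10.8 and 0.0671 ± 0.0263, and the mitochondrial aldehyde dehydrogenase gene ALDH1B1 at 19.0 and 0.602 ± 0.119. TOR4A stood at 34.1 and 2.15 ± 0.651, FAM89A at 10.8 and 0.124 ± 0.0774, the mitotic helicase gene ERCC6L at 14.3 and 1.03 ± 0.749, and ZNF358 at 15.2 and 0.785 ± 1.05. CCDC85B (43.7 FPKM in con-sh), the arginine methyltransferase gene PRMT6 (8.77) and the mitochondrial methionyl-tRNA synthetase gene MARS2 (4.94) were listed at 0 in both knockdown libraries. Of these lower genes, TIMP2, SDC4 and IFIT2 have 5 annotated exons and the others 1 to 3. The limma adjusted p of the lower genes was 0.11 to 0.49. The value of 0.11 was that of CCDC85B alone. For the genes listed at 0 in both knockdown libraries, the p measures no spread between them.

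**Figure D1:**
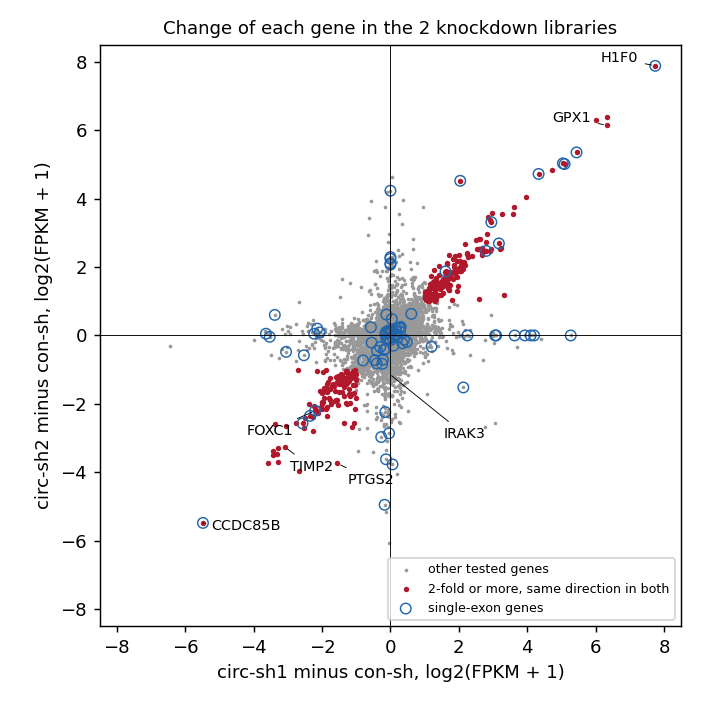
Difference of each of 9946 genes from the control library on the log2(FPKM + 1) scale, circ-sh1 on the x axis and circ-sh2 on the y axis, with the 286 genes at least 2-fold apart in the same direction in both in red and single-exon genes circled. Pearson's r was 0.509 across genes, and some single-exon genes lie far from 0, both along the diagonal and along each axis.

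The 3 libraries were about equally far apart. Pearson's r of log2(FPKM + 1) across genes was 0.925 between circ-sh1 and circ-sh2, 0.924 between con-sh and circ-sh1 and 0.922 between con-sh and circ-sh2, and Spearman's rho was 0.913, 0.917 and 0.912 in that order. By size, 664 genes were at least 2-fold from control in circ-sh1, 686 in circ-sh2, and 657 were 2-fold apart between the 2 knockdown libraries. Setting each library against the other 2, con-sh stood apart by 2-fold in 286 genes, circ-sh1 in 268 and circ-sh2 in 278. Across genes, the fold changes of the 2 knockdown libraries had a Pearson's r of 0.509 and a Spearman's rho of 0.386, where unchanged libraries with a shared control gave a Pearson's r of 0.5 (95% range 0.473 to 0.527) and a Spearman's rho of 0.467 (0.45 to 0.484). The share of genes with the same sign in both was 62% against 66.6% simulated (65.7 to 67.5), so rho and this share lay below the values simulated with no effect. Their covariance was 0.178 against 0.172 simulated (0.157 to 0.187), a difference of 0.00603. The control could not be split, so part of any excess may come from it. The genes with the largest differences between the knockdown libraries were IER3, an immediate early gene (869 FPKM in con-sh, 9.04 in circ-sh1 and 702 in circ-sh2), IER2 (0.0798, 0.118 and 26.0) and IFIT3 (0.794, 0.206 and 26.5), all lower in circ-sh1. PYURF (70.0, 68.7 and 0.0585), RNASEK-C17orf49 (6.15, 58.2 and 0.216) and CKAP4 (5.54, 43.1 and 0.0235) were lower in circ-sh2. IER3, IER2, IFIT3 and PYURF have 2 annotated exons and CKAP4 has 4. RNASEK-C17orf49 overlaps 2 other listed genes on the same strand. These values are therefore uncertain too, and may be failed or divided estimates.

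Of 31 lists tested with camera at the preset correlation, 6 were lower in the knockdown libraries (interferon stimulated genes, inflammatory and NF-kB target genes, lung metastasis associated genes, matrix proteases and their inhibitors, hypoxia response and forkhead factors) and 3 were higher (YAP and TAZ targets, G2 and mitosis genes, and heat shock and NRF2 genes). With an estimated correlation, 0 lists passed and the adjusted p was 0.87 for each of these 9. That version rests on 1 residual degree of freedom. Whichever library was set against the other 2, no list reached even an unadjusted p under 0.05 with it. It could hardly pass a list here, so its outcome speaks neither for nor against one. The preset version assumes almost uncorrelated members, so its p-values may be too small. It also takes genes and not cultures as the replicates, so its p-values make no allowance for differences between cultures. The unadjusted estimated-correlation p is given beside each list below. In none of these lists did a member pass limma's test over all genes, so members are given as values. An adjustment over the members of 1 list alone, given below, was not part of the design fixed in advance. It makes no allowance for the number of lists. Set against the other 2 libraries in the same way, circ-sh1 gave 2 lists and circ-sh2 gave 4, and with an estimated correlation each gave 0.

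Interferon stimulated genes, which act in antiviral defence, were lower as a group (camera adjusted p = 0.00026; p = 0.13 with an estimated correlation). Of 26 members, 17 were lower and 1 higher in both knockdown libraries, with medians of -0.38 in circ-sh1 and -0.39 in circ-sh2, both below the medians of all 10000 random lists, which describes these libraries only, as both share the 1 control. IFI44 stood at 22.8 FPKM in con-sh and 8.86 ± 1.56 in the knockdown group, OASL at 15.1 and 6.38 ± 0.315, and BST2, which encodes the virus-tethering protein tetherin, at 6.33 and 3.43 ± 0.147; IFIT2 is given above. The member higher in both was ISG15, a ubiquitin-like modifier, at 8.17 FPKM in con-sh and 55.5 ± 2.9 in the knockdown group. Members that went different ways in the 2 libraries included IFIT3, at 0.794 FPKM in con-sh, 0.206 in circ-sh1 and 26.5 in circ-sh2. Over all genes 0 members passed limma's test, and 2 passed when adjusted over the list alone, IFIT2 (lower) and ISG15 (higher). With a mean of at least 5 FPKM, 13 members remained and the camera adjusted p was 0.25.

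Inflammatory and NF-kB target genes, mainly cytokines and chemokines, were also lower (camera adjusted p = 0.00075; p = 0.14 with an estimated correlation). Of 24 members, 15 were lower and 1 higher in both libraries, and the medians were -0.34 in circ-sh1 and -0.44 in circ-sh2. PTGS2, the inducible cyclooxygenase, stood at 97.0 FPKM in con-sh, 32.5 in circ-sh1 and 6.34 in circ-sh2. The chemokine gene CXCL3 was at 23.6, 9.92 and 5.26 FPKM, CSF2, which encodes GM-CSF, at 104, 26.9 and 61.3, and the chemokine gene CXCL1 at 237, 135 and 164. The member higher in both was CXCL2, at 13.8, 21.4 and 30.1 FPKM. No member passed limma's test over all genes or when adjusted over the list alone. This list also separated circ-sh2 from the other 2 libraries (camera adjusted p = 0.0092; adjusted p = 0.89 with an estimated correlation), with lower values in circ-sh2. The 18 tested genes of Toll-like and interleukin 1 receptor signalling, the pathway in which the IRAK3 protein acts, did not pass (camera adjusted p = 0.94), with medians of -0.01 and 0.11.

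Genes associated with lung metastasis of breast cancer were lower (camera adjusted p = 0.0076; p = 0.18 with an estimated correlation), with 11 of 20 members lower and 2 higher in both and medians of -0.23 and -0.34. The list gives no direction of association for its members, so lower values do not mean a lower capacity for metastasis. It shares members with the others: PTGS2 and CXCL1 with the inflammatory list, MMP1 and MMP2 with the proteases and ANGPTL4 with hypoxia. Matrix proteases and their inhibitors were lower (camera adjusted p = 0.027; p = 0.21 with an estimated correlation), with 9 of 16 members lower and 4 higher in both and medians of -0.16 and -0.27. The members with the largest differences were of opposing function: beside the inhibitor TIMP2, the interstitial collagenase MMP1 stood at 156 FPKM in con-sh and 61.5 ± 1.47 in the knockdown group, the membrane-bound MMP14 at 168 and 96.5 ± 1.38, and stromelysin MMP3 at 16.5 and 6.59 ± 4.61. When adjusted over the list alone, 2 members passed, TIMP2 and MMP1. Collagens and matrix glycoproteins did not pass (camera adjusted p = 0.44), nor did integrins and adhesion genes (0.55), mesenchymal genes (0.48) or epithelial genes (0.97). Of the mesenchymal genes, 1 passed when adjusted over the list alone, FOXC1, which was listed at 0 in both knockdown libraries, so its p measures no spread between them.

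Genes of the hypoxia response, induced by HIF factors, were lower (camera adjusted p = 0.017; p = 0.19 with an estimated correlation). Of 22 members, 12 were lower and 2 higher in both, and the medians were -0.37 and -0.26. Carbonic anhydrase CA9 stood at 15.1 FPKM in con-sh and 6.5 ± 1.18 in the knockdown group, ANGPTL4 at 13.2 and 6.24 ± 0.816, NDRG1 at 59.4 and 32.3 ± 5.83, and the angiogenic factor VEGFA at 28.6 and 13.8 ± 5.06. EGLN1, an oxygen sensor that marks HIF for degradation, was higher, at 5.02 and 15.6 ± 1.3. Glycolysis genes (camera adjusted p = 0.086) and angiogenesis factors (0.086) did not pass. The forkhead list was lower (camera adjusted p = 0.0058; p = 0.18 with an estimated correlation), with 8 of 13 members lower and 1 higher in both. Its medians were -0.32 in circ-sh1 and -0.2 in circ-sh2, at percentiles 0.25 and 3.04 of random lists. It contains FOXC1, and FOXF2 stood at 4.33 FPKM in con-sh and 0.839 ± 0.216 in the knockdown group, FOXO3 at 2.82 and 1.37 ± 0.113 and FOXP4 at 12.5 and 8.78 ± 0.796. When adjusted over the list alone, 2 members passed, FOXC1 and FOXF2. FOXC1 was listed at 0 in both knockdown libraries, so its p measures no spread between them. Among the 9 members with 5 or more exons, which leave FOXC1 out, the camera adjusted p was 0.49, and with a mean of at least 5 FPKM it was 0.25.

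YAP and TAZ target genes, the transcriptional output of the Hippo pathway, were higher (camera adjusted p = 0.0058; p = 0.35 with an estimated correlation), with 8 of 14 members higher and 1 lower in both and medians of 0.49 and 0.29. FJX1 stood at 14.0 FPKM in con-sh and 33.1 ± 2.43 in the knockdown group, the receptor tyrosine kinase AXL at 67.1 and 110 ± 8.78, ANKRD1 at 30.3 and 45.9 ± 3.6, and ARHGEF17 at 1.16 and 2.17 ± 0.211. This list also separated circ-sh1 from the other 2 libraries (camera adjusted p = 0.011; adjusted p = 0.96 with an estimated correlation), with higher values in circ-sh1, and with a mean of at least 5 FPKM its camera adjusted p was 0.06. TGF beta targets did not pass (camera adjusted p = 0.91), with medians of 0.2 and -0.36.

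Genes of the G2 phase and mitosis were slightly higher (camera adjusted p = 0.0058; p = 0.23 with an estimated correlation): 20 of 30 members were higher and 2 lower in both, with medians of 0.07 in circ-sh1 and 0.25 in circ-sh2. Among random lists these lay at percentiles 78.93 and 100, so in circ-sh1 alone the median did not stand apart. The mitotic kinesin KIF2C stood at 52.8 FPKM in con-sh and 71.7 ± 0.937 in the knockdown group, CENPE at 6.77 and 10.1 ± 1.31, KIF20A at 43.1 and 58.7 ± 3.86 and TPX2 at 106 and 137 ± 3.66. The list also separated circ-sh2 from the other 2 libraries (camera adjusted p = 0.0092; adjusted p = 0.89 with an estimated correlation), with higher values in circ-sh2. Genes of DNA replication did not pass (camera adjusted p = 0.4). Heat shock and NRF2 genes were higher (camera adjusted p = 0.028; p = 0.4 with an estimated correlation), with 12 of 19 members higher and 1 lower in both. The medians were 0.2 in circ-sh1 and 0.08 in circ-sh2, at percentiles 99.57 and 84.67 of random lists, so in circ-sh2 alone the median did not stand apart. The small heat shock protein gene HSPB1 stood at 7.41 FPKM in con-sh and 53.9 ± 11.4 in the knockdown group, the cystine transporter gene SLC7A11 at 8.66 and 15.3 ± 3.41, TXNRD1 at 37.8 and 58.3 ± 5.17 and NQO1 at 105 and 137 ± 4.8; HSPB1, which has 3 exons, was the 1 member that passed when adjusted over the list alone, and among the 12 members with 5 or more the camera adjusted p was 0.15.

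**Figure D2:**
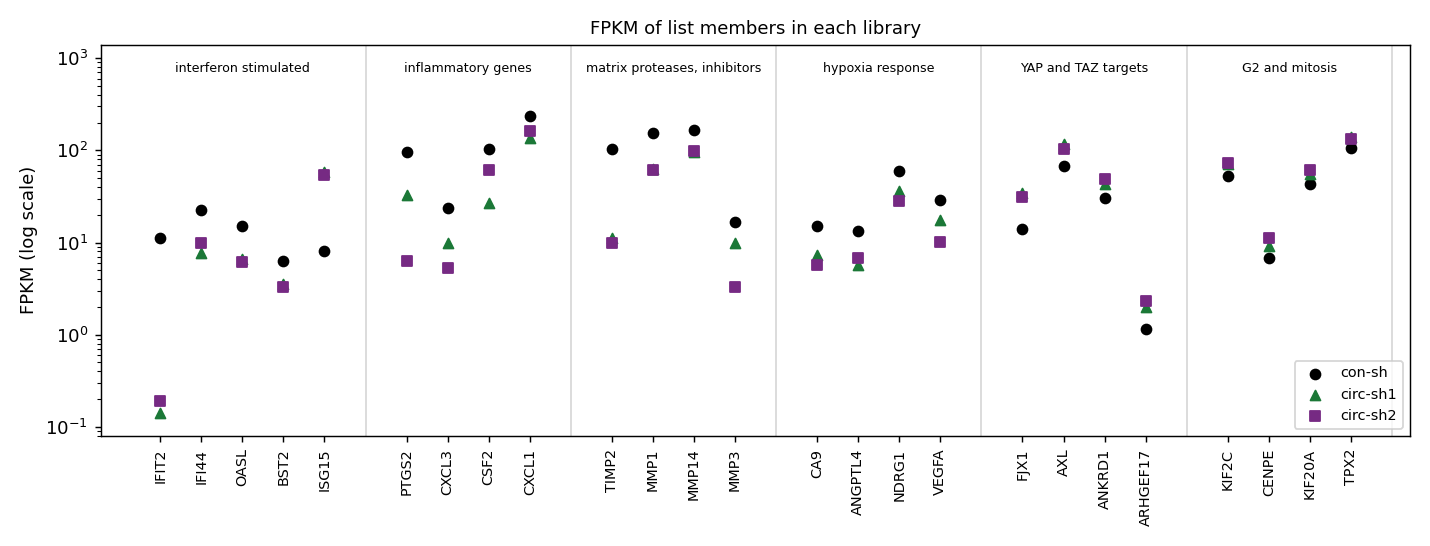
FPKM (log scale) of members of 6 gene lists in con-sh (circles), circ-sh1 (triangles) and circ-sh2 (squares), 1 value per library. IFI44, OASL, MMP1 and CA9 lie lower in both knockdown libraries and FJX1, AXL and ISG15 lie higher, while PTGS2 and MMP3 also differ between circ-sh1 and circ-sh2.

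**Figure D3:**
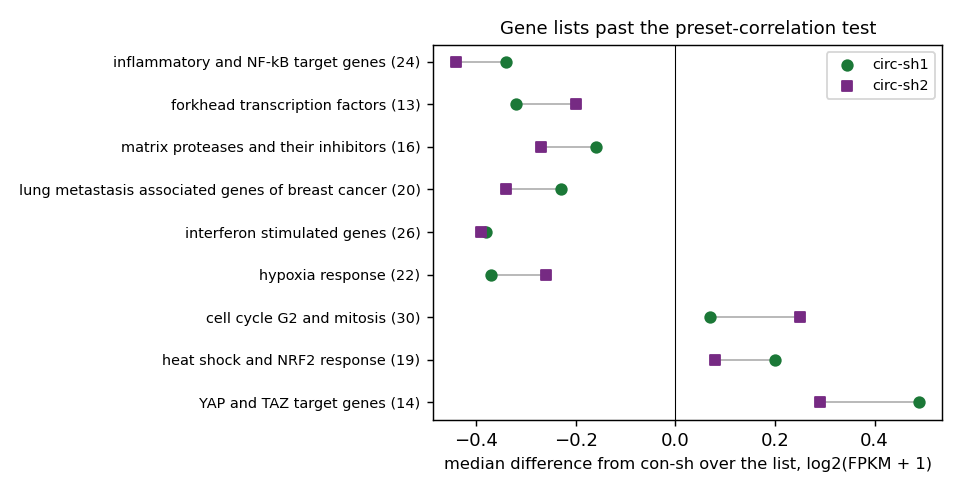
Median difference from the control library over the members of the 9 lists that passed camera with the preset correlation, in log2(FPKM + 1), for circ-sh1 (circles) and circ-sh2 (squares), with the number of tested members in brackets. The medians run from -0.44 for inflammatory genes in circ-sh2 to 0.49 for YAP and TAZ targets in circ-sh1.

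The remaining lists did not pass camera. The adjusted p was 0.4 for ATF4 and amino acid response genes, 0.44 for p53 targets, 0.44 for MHC class I genes, 0.55 for immediate early genes, 0.55 for microRNA processing factors, 0.55 for RNA-binding proteins of circular RNA formation, 0.65 for apoptosis regulators, 0.88 for EGFR family genes, 0.91 for cholesterol synthesis and 0.97 for the unfolded protein response. Cytosolic ribosomal proteins (0.87; medians 0.07 and -0.06) and nuclear oxidative phosphorylation genes (0.48; medians 0.09 and 0.02) did not pass either. The sign of the mean, the medians and the test did not all match for the epithelial, integrin, TGF beta, immediate early, Toll-like receptor, apoptosis, cholesterol, unfolded protein, EGFR and ribosomal lists, none of which passed. As a check for other cells, the 6 tested luminal breast markers had an adjusted p of 0.44 and medians of -0.12 and -0.1. Of lists with fewer than 5 tested members, single genes are given as values. GATA2, 1 of 2 tested members of the kidney and embryonic list, stood at 1.34 FPKM in con-sh, 1.28 in circ-sh1 and 1.47 in circ-sh2. The fibroblast marker COL1A1 was at 6.54, 11.2 and 7.5 FPKM, the blood cell marker CD68 at 57.4, 39.7 and 48.6 and CD14 at 1.1, 1.42 and 0.61, and the endothelial marker ESAM at 48.9, 47.7 and 40.5. Of the other short lists, the metallothionein genes went different ways, with MT1E at 53.6, 92.2 and 68.5 FPKM, MT2A at 328, 436 and 296, MT1X at 30.3, 32.6 and 22.1 and MT1F at 5.61, 5.43 and 4. The mitochondrial gene MT-ND5 stood at 568, 531 and 602 FPKM, whereas MT-CYB stood at 1160, 92.4 and 1200. The replication-dependent histone gene HIST2H2AA3 was at 6.87, 3.53 and 4.14 FPKM and HIST1H2AC at 3.2, 2.86 and 2.58. None of the members of the nuclear RNA list was among the protein-coding genes of the table.

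**Figure D4:**
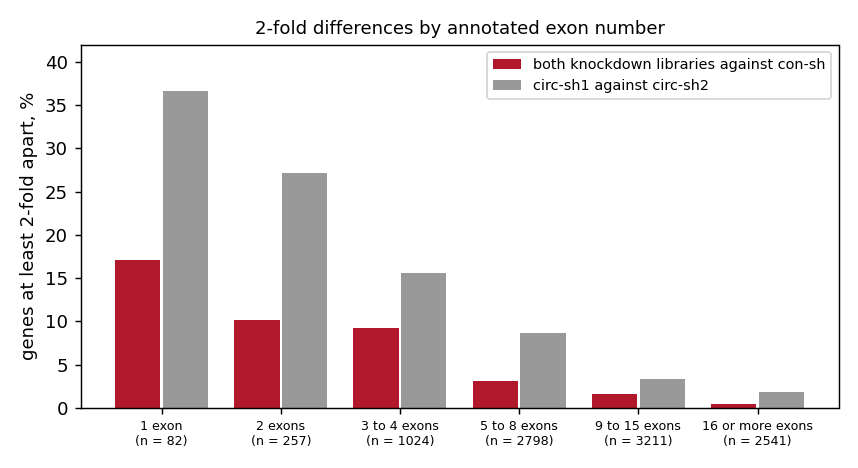
Share of tested genes at least 2-fold apart (%), by the largest annotated number of exons, for both knockdown libraries against con-sh in the same direction (red) and for circ-sh1 against circ-sh2 (grey). Both shares are highest in single-exon genes (17.1% and 36.6%) and lowest in genes with 16 or more exons (0.394% and 1.77%).

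Both kinds of 2-fold difference depended on the exon number of the gene. Of 82 tested single-exon genes, 14 (17.1%) were 2-fold from control in both knockdown libraries and 30 (36.6%) differed 2-fold between the 2 knockdown libraries. Of 2541 genes with 16 or more exons, 10 (0.394%) and 45 (1.77%) did so. Among single-exon genes that reached 3 FPKM, 21 were listed at 0 in con-sh, 16 in circ-sh1 and 19 in circ-sh2.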

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

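The restriction to genes with 5 or more exons was chosen after seeing the data, the other alternatives before. The fit called 0 genes under each of the 7 alternatives run (pseudocount 0.1, no filter, mean of at least 5, trimmed mean scaling, quantile normalization, no trend and genes with 5 or more exons); the lowest adjusted p lay between 0.053 with a pseudocount of 0.1 and 0.14 with trimmed mean scaling. Requiring a mean of at least 5 FPKM gave 190 genes 2-fold from control in both libraries, 427 in circ-sh1, 427 in circ-sh2 and 411 between the knockdown libraries, fewer genes being tested. Genes with 5 or more exons gave 149, 388, 401 and 395, and a size of 1.5-fold gave 592, 1381, 1421 and 1522. Leaving out 1 knockdown library gave 664 to 686 genes, as only 1 library then had to differ. Correlation of the fold changes moved to 0.523 with a mean of at least 5 and to 0.476 with 5 or more exons. With an estimated inter-gene correlation the number of lists past the threshold was 0 in place of 9. That setting has 1 residual degree of freedom and could hardly pass a list. Of the single lists, 3 lost the call with a mean of at least 5 (YAP and TAZ targets, interferon and forkhead), 2 with 5 or more exons (heat shock and forkhead) and glycolysis gained it (adjusted p 0.027); none past the threshold reversed, while TGF beta and cholesterol genes (mean of at least 5) and epithelial and unfolded protein genes (5 or more exons), which did not pass, changed direction. With a pseudocount of 0.1, no filter or trimmed mean scaling all 31 kept their call and direction. The higher share of the 286 genes was 55.9%, against 63.7% (121 higher, 69 lower) with a mean of at least 5 and 49.7% (74 and 75) with 5 or more exons. IRAK3 was -0.05 without circ-sh2 and -1.11 without circ-sh1; FOXC1 was listed at 0 in each, so no fold change is given. FOXC1 was outside 2 settings, the mean of at least 5 and the exon limit, and IRAK3 outside the first. With 1 library against 1 there is no residual degree of freedom, so the fit and camera gave no value without a knockdown library. Alternatives planned for counts were not run, as the table holds FPKM. No paired analysis was possible because the control has 1 library and no number in its title. Depth is unknown, so how far counting error limits these values cannot be stated.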

Other observations

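The comparisons of each knockdown library with the other 2 and the tests of explanations in this part were chosen after the results were seen, except that the list test of knockdown against control, its estimated correlation and the mean of at least 5 FPKM were planned. Between the 2 knockdown libraries, cytosolic ribosomal protein genes stood highest in circ-sh1 (camera with the preset correlation, adjusted p = 0.011 against the other 2 libraries) and lowest in circ-sh2 (0.0092). Their medians against con-sh were 0.07 and -0.06. DNA replication genes stood highest in circ-sh2 (0.021), with a median of 0.08 against con-sh. With an estimated correlation 0 lists passed in any of these comparisons, but that version could hardly pass a list. MT-CYB, a mitochondrial gene of the respiratory chain, stood at 92.4 FPKM in circ-sh1 against 1160 in con-sh and 1200 in circ-sh2, while MT-ND5 differed little (531, 568 and 602 FPKM in that order).

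The 286 genes 2-fold from control in both knockdown libraries are the pattern a reader would take first as the response to the knockdown. Weak expression does not account for all of it, as 64 of the 286 genes had a mean of 20 FPKM or more. By FPKM ratios without a pseudocount, which would damp weak genes, the share at that level (3.55% of 1857) was 0.819 times that at 1 to 5 (4.34% of 4079). Those ratios do not select the same set of genes as the 286. FPKM is scaled by length and depth is unknown, so few reads in short transcripts at a higher FPKM are not excluded. A candidate explanation is an abundance estimate that fails, or is divided between overlapping transcripts, in genes with few exons: 2-fold differences between the knockdown libraries themselves were 4.13 times as frequent with 1 to 4 exons (19.1% of 1363) as with 5 or more (4.62% of 8550). An effect common to both libraries stays open, as the covariance exceeded the simulated one by only 0.00603, inside its range. With genes of 5 or more exons it was 0.0959 against 0.106 simulated (0.0978 to 0.114), a difference of -0.00983. That covariance, the Spearman's rho of 0.386 (0.45 to 0.484 simulated) and the same-sign share of 62% (65.7 to 67.5 simulated) lay below the simulated ranges. The equal spread in all 3 libraries that the simulation assumes may therefore not hold, and the comparison decides nothing. Only 3 choices of the lone library exist, too few for a share under 0.05; the real choice gave 286 genes and the highest other 278 (1 of 3 choices as large).

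FOXC1 was listed at 0 in both knockdown libraries and at 3.59 FPKM in the control. A failed estimate of a single-exon gene is a candidate explanation: 55.7% of single-exon genes that reached 3 FPKM were listed at 0 in some library, among them H1F0, which stood at 213 and 235 FPKM in the libraries where it was not. Less FOXC1 RNA in the knockdown cells cannot be told apart from this, because 4 single-exon genes were listed at 0 in both knockdown libraries alone (FOXC1, MOCS3, CCDC85B and MARS2) and 8 in the control alone, and no read counts were used here. A count of reads over the FOXC1 exon in each library would separate the explanations.

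As groups, interferon stimulated genes (17 of 26 members lower in both knockdown libraries) and inflammatory genes (15 of 24) were lower by camera with the preset correlation. With an estimated correlation neither passed (camera adjusted p = 0.87 for each), but with 1 residual degree of freedom that version could hardly pass a list. ISG15 and CXCL2 were higher in both knockdown libraries. Misestimated genes with 1 to 4 exons do not alone account for the interferon medians. With genes of 5 or more exons these were again -0.38 and -0.39. Among these 20 members the camera adjusted p was 3.6e-07 with the preset correlation and 0.9 with an estimated one. With a mean of at least 5 FPKM and any exon number it was 0.25. Misestimated members with more exons are not excluded. IFIT2, with 5 exons, stayed in, and 8.68% of genes with 5 to 8 exons differed 2-fold between the knockdown libraries. For the inflammatory list, misestimated genes with few exons cannot be told apart from a shift of the group. Without such genes its circ-sh1 median went from -0.34 to -0.12 and its circ-sh2 median from -0.44 to -0.37. Its camera adjusted p was then 0.0025 with the preset correlation and 0.9 with an estimated one. A control library that differs for a reason other than the circular RNA, such as culture density or the control hairpin itself, cannot be told apart from an effect of the knockdown, because the adjusted p of 0.00026 for the interferon list rests on 1 control, and with 3 choices of the lone library (9 lists for the real one, at most 4 for the others, 1 of 3 as large) no share under 0.05 can be had. That the knockdown may lower interferon output is a hypothesis these libraries cannot test, and replicated control cultures would be needed.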
